A study of Homo sapiens with 6 samples.

How the data were processed

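Poly(A) RNA sequencing of 6 libraries from SH-SY5Y cells, a human neuroblastoma line with catecholaminergic features, was analysed. Per the labels' protocols, cells were grown in DMEM with 10% fetal bovine serum and 1% penicillin and streptomycin in 10 cm dishes to 80% confluence, then given 2 ul of an adenovirus carrying either GFP or PGC-1a for 48 h. RNA was extracted with Trizol, and libraries were made by a poly(A) method with a module that retains strand, per the labels' protocols. The titles place 3 libraries in each group, named GFP and PGC1A here, with replicate numbers 1 to 3. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

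The deposited table holds raw read counts per gene for all 6 libraries in 1 file. The submitters' processing notes name DRAGEN, STAR 2.6.0c, HTSeq 0.10.0, DESeq2 1.20.0 and the GRCh38 build, without giving their order or settings. The annotation release and the strand setting of the counting are not given in the sources used here. Reads from a gene and its antisense partner therefore cannot be assumed to be separated. The 5 summary lines that HTSeq writes after the genes were in the table and held 28.8% to 31.0% of its reads in each library. They were kept out of library sizes and tests. The reads not assigned to 1 gene include those with several alignments (13.9% ± 0.418 of the reads in the table in the GFP libraries and 12.7% ± 0.244 in the PGC1A libraries, SD, n = 3), so genes with near-identical copies are undercounted. No column of values was left without a sample.

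Gene IDs were matched to GENCODE 29, which is on GRCh38. Of the 58096 gene rows, 57492 IDs were found there, 53706 with the same version, and 57447 rows received a symbol. Coordinates given here come from that annotation, counted from 1.

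Counts assigned to genes ranged from 24988743 to 31762496 per library. At this depth a floor of 3 counts was used for groups without reads. Fold changes against such a group are lower bounds computed with 3 counts over the whole group, and they cover counting error only. Ratios with 1 to 3 counts in a group are given with 95% counting intervals. PCR copies were not marked by molecular identifiers, so intervals and floors do not include amplification error.

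The main test was edgeR 4.0.16 (R 4.3.3) with TMM factors, the filterByExpr default (minimum count 10, total 15), glmQLFit with robust estimation and glmQLFTest, with group as the only term and Benjamini-Hochberg adjustment over the 19343 genes tested (threshold 0.05, two-sided). Fold changes are PGC1A over GFP. CPM values are TMM-normalised. For each of 28 gene lists, camera in limma 3.58.1 tested log2 CPM (prior count 2) with an inter-gene correlation preset at 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The estimated version of camera uses the 4 residual degrees of freedom of the fit, and the preset version uses many more. The test, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took PPARGC1A, ESRRA, PPARGC1B and PPRC1. It then took the 6 protein-coding genes with the largest rise and the 6 with the largest fall among genes past the threshold whose groups did not overlap and whose mean was at least 5 CPM. For each list it took up to 2 members with the largest change in the prevailing direction and 1 in the other, at a mean of at least 1 CPM. A gene that the rule took is not reported here. The mean log2 CPM of the nuclear-encoded OXPHOS list minus that of the mtDNA-encoded list was compared between groups with an exact permutation test, for which 3 against 3 libraries give a smallest two-sided p of 0.1.

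The edgeR procedure was tested on simulated data for the PGC1A against GFP comparison, with 5 draws of 19343 genes that each held 200 changed genes. It recovered 73.2% of 1.2-fold, 94.8% of 1.5-fold, 99.2% of 2-fold and 100% of 4-fold changes, and 77 of 995 calls (7.74%) were false, more than the nominal rate. The number of draws was raised to 5 after the false calls of a single draw had been seen, and that draw is among the 5. In a simulated shift of 0.5 (log2) of the peroxisome list, camera gave an adjusted p of 9.48e-82 for that list, or 8.24e-04 with an estimated correlation, and called 0 other lists. Both simulations drew genes independently and left most of them unchanged, whereas 83.0% of genes passed in the real comparison. Their results therefore may not carry over to the real data or to lists of correlated members.

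The alternatives were DESeq2-type size factors, upper-quartile factors or total counts in the edgeR fit, PPARGC1A or the mitochondrial genome left out of the factors, no filter beyond 1 count, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, edgeR without robust estimation, glmTreat against a 1.5-fold change, the replicate number as a block, and each library left out in turn. Overlaps of exons between genes, transcript length and GC content came from the GENCODE 29 annotation and the reference. Fisher's exact and permutation tests were run in Python 3.11.15 with scipy 1.17.1.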

Results

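Expression was measured by RNA sequencing in SH-SY5Y neuroblastoma cells 48 h after delivery of 2 ul of adenovirus, with 3 libraries given GFP and 3 given PGC-1a (groups GFP and PGC1A). PGC-1a, encoded by PPARGC1A, is a transcriptional coactivator known for driving mitochondrial biogenesis. The series examines how gene expression changes when PGC-1a is expressed in these cells, which makes PGC1A against GFP the comparison of interest. The labels give equal volumes of the viruses but no titre, and no uninfected library was analysed here, so a difference in dose between the viruses cannot be separated from PGC-1a. Counts assigned to genes averaged 28831163 ± 3477570 in GFP and 29406384 ± 1027124 in PGC1A (SD, n = 3). The shallowest library was GFP replicate 1 with 24988743 counts, and the deepest was GFP replicate 3 with 31762496. Replicates resembled each other closely, with correlations of log2 CPM across genes of 0.995 to 0.996 within groups against a mean of 0.894 between groups (genes are not independent replicates). Every replicate pair differed by more than counting noise, with a chi-square per degree of freedom of 1.25 to 2.81, so no library was a copy of another. The biological coefficient of variation was 2.21%, and the first principal component held 94.7% of the variance.

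PPARGC1A (ENSG00000109819.8, chromosome 4, 23755041 to 23904089, GRCh38) had 98, 131 and 135 counts in the GFP libraries and 109350, 104546 and 103737 in the PGC1A libraries. Its mean rose from 3.75 ± 0.233 to 4042 ± 61.9 CPM (SD, n = 3), a log2 fold change of 10.07 (SE 0.04, adjusted p = 2.06e-70, edgeR quasi-likelihood test). The transcript took 0.360% ± 0.00551 of gene counts in PGC1A. The labels do not give the species or the untranslated parts of the virus insert, so the count may cover only part of the delivered transcript. ESRRA (ENSG00000173153.13), the estrogen-related receptor through which PGC-1a is known to act on mitochondrial genes, rose from 48.5 ± 1.27 to 208 ± 4.35 CPM (log2 fold change 2.10, SE 0.03, adjusted p = 1.14e-46). The related coactivator PPARGC1B fell by 1.84 on the log2 scale (SE 0.21, adjusted p = 5.31e-11), from 2.37 to 0.662 CPM. PPRC1, the third member of the family, fell by 0.21 (SE 0.04, adjusted p = 7.12e-07), a change too small to pass a test against a 1.5-fold change (glmTreat adjusted p = 1).

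Most of the measured transcriptome differed between the groups. Of 19343 genes tested, 16057 (83.0%) passed an adjusted p of 0.05, with 7909 higher and 8148 lower in PGC1A. Changes of at least 2-fold were seen in 3681 higher and 3258 lower genes, of at least 4-fold in 1550 and 845, and of at least 10-fold in 630 and 159. The groups did not overlap in 16180 genes (83.6%, where chance gives 10%). Tested against a 1.5-fold change with glmTreat, 9241 genes passed, 4766 higher and 4475 lower. The direction split depends on the scaling. Against 7909 higher and 8148 lower with TMM (49.3% higher), DESeq2-type size factors gave 8179 and 7869, upper-quartile factors gave 7047 and 9234, and total counts gave 5778 higher and 10743 lower. The DESeq2 Wald test gave 7715 higher and 7313 lower. The balance at 2-fold turned as well, to 3276 higher and 3864 lower with upper-quartile factors and 2746 higher and 4944 lower with total counts. Total counts moved the median of all genes by −0.33 (log2) and upper-quartile factors by −0.13, so the balance of directions is relative to the TMM scaling.

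The 6 genes with the largest rises were nearly silent in GFP. DMKN (dermokine, a secreted epidermal protein) had no counts in GFP and 43.7 ± 1.97 CPM in PGC1A (SD, n = 3), at least 1409-fold higher. PSG3 (a pregnancy-specific glycoprotein, 26.3 CPM), HOXC12 (a homeobox gene, 19.2 CPM), SLC18B1 (a vesicular polyamine transporter, 18.3 CPM) and PYDC1 (a pyrin-domain protein, 17.9 CPM) also had no GFP counts and were at least 849-fold, 620-fold, 592-fold and 579-fold higher. PVALB, the calcium-binding protein parvalbumin of fast-spiking interneurons and fast muscle, had 5 counts over the GFP libraries and 18703 over the PGC1A libraries, reaching 238 ± 11.7 CPM. PSG3 has near-identical paralogs, so its count is uncertain. The histone gene H4C5 had the largest fall, a log2 fold change of −6.21 (SE 0.13), from 25.7 to 0.345 CPM. SLC18A1, the vesicular monoamine transporter of chromaffin cells, fell by 4.85 (37.3 to 1.29 CPM), and DRGX, a homeobox gene of sensory neurons, fell by 4.76. The synaptic vesicle protein genes SYT5 and SLC10A4 fell (−4.20 and −4.05), as did CHRNA3, a nicotinic acetylcholine receptor subunit, from 138 to 8.60 CPM. Adjusted p-values of these 12 genes ranged from 1.48e-54 for PVALB to 2.93e-32 for SYT5 (edgeR).

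**Figure D1:**
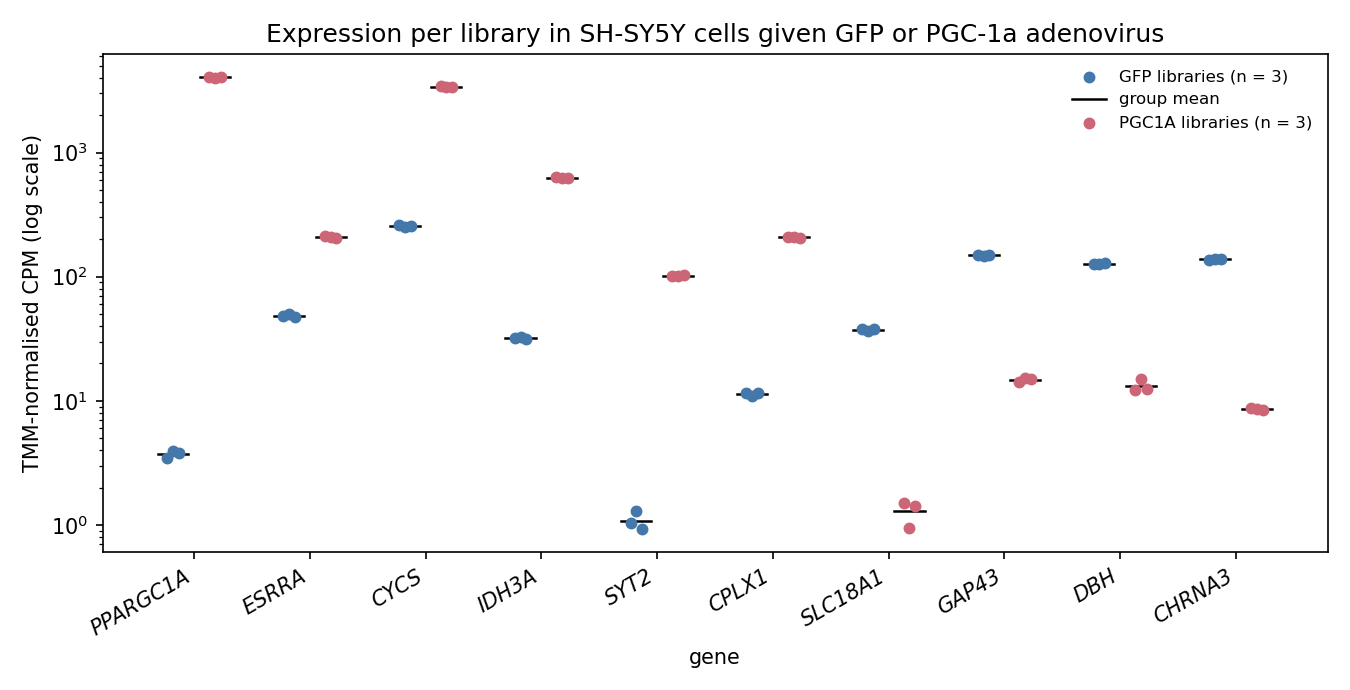
TMM-normalised CPM on a log axis for 10 genes in each of the 3 GFP and 3 PGC1A libraries (points), with group means as lines. PPARGC1A, ESRRA, CYCS, IDH3A, SYT2 and CPLX1 were higher and SLC18A1, GAP43, DBH and CHRNA3 lower in all 3 PGC1A libraries than in any GFP library.

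Respiratory chain transcripts rose almost without exception. Of 77 nuclear-encoded subunits of oxidative phosphorylation (OXPHOS) and cytochrome c, 75 were higher and 1 lower, with a median log2 fold change of 2.03. CYCS (cytochrome c) rose from 257 ± 5.55 to 3381 ± 44.4 CPM (3.72 on the log2 scale) and SDHB, the iron-sulfur subunit of succinate dehydrogenase, rose by 3.55 on the log2 scale. NDUFA13, of complex I, was the exception and fell by 0.66 (glmTreat adjusted p = 0.204); 21.0% of its exon bases also lie in another gene on the same strand, which makes its count uncertain. All 13 mtDNA-encoded mRNAs were higher, with a median of 1.13, MT-ND1 by 1.59 and MT-ND6 by 1.53 (log2), and mitochondrial genome transcripts took 13.9% ± 0.256 of gene counts in PGC1A against 6.65% ± 0.216 in GFP. The set test (camera) gave adjusted p = 9.03e-19 for the nuclear list and 6.00e-05 for the mtDNA list. With an estimated correlation neither call held (adjusted p = 0.232 and 0.384). The mean over the nuclear list rose by 2.02 (log2) and that over the mtDNA list by 1.10. The difference between the lists went from −5.71 ± 0.044 in GFP to −4.79 ± 0.018 in PGC1A (SD, n = 3), a shift of 0.92, with an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. mtDNA-encoded genes have nuclear pseudogene copies that can take some of their reads.

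**Figure D2:**
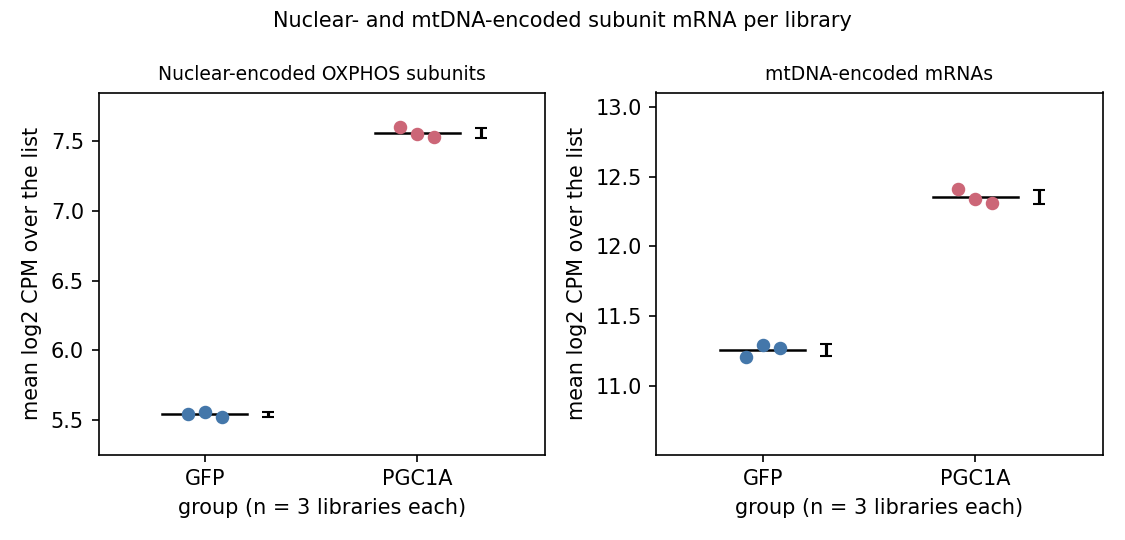
Mean log2 CPM over the 77 nuclear-encoded OXPHOS subunits (left) and the 13 mtDNA-encoded mRNAs (right) in each library (points), with group means (lines) and SD (bars, n = 3); both panels span the same number of log2 units. The nuclear list rose by 2.02 and the mtDNA list by 1.10.

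The pathways that feed the respiratory chain rose as well. All 21 genes of the tricarboxylic acid cycle and pyruvate dehydrogenase were higher by at least 2-fold, with a median log2 fold change of 2.76. MPC1, a subunit of the mitochondrial pyruvate carrier, rose from 17.8 ± 1.15 to 747 ± 23.1 CPM (5.39 on the log2 scale), and IDH3A, of isocitrate dehydrogenase, rose by 4.29. Of 22 genes of mitochondrial fatty acid oxidation, 21 were higher and 0 lower (median 2.19), with ACADSB, a short branched-chain acyl-CoA dehydrogenase, up by 4.27 and ETFDH, which passes electrons to ubiquinone, up by 3.78 (log2). Camera gave adjusted p = 4.87e-10 and 1.64e-08 for these lists, and adjusted p = 0.0792 for each with an estimated correlation. IDH3A shares 38.9% of its exon bases with genes on either strand, and the strand setting of the counting is not known.

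Genes that build and maintain mitochondria rose too, with smaller medians. Of 77 mitochondrial ribosomal protein genes, 73 were higher and 1 lower (median 1.06), with MRPL2 up by 2.77 and MRPL48 down (−0.57, glmTreat adjusted p = 0.603). MRPS24 rose by 3.53 but has 23.2% of its exon bases in another gene and reached only 5.43 CPM. Of 18 genes of mtDNA maintenance, transcription and fusion, 17 were higher and 1 lower (median 0.49). The fusion GTPase gene OPA1 rose by 2.35 and LRPPRC, which stabilises mitochondrial mRNA, by 2.15, while POLG2, the accessory subunit of the mtDNA polymerase, changed by −0.54 (glmTreat adjusted p = 0.984). With total counts 12 of these 18 were higher and 4 lower. Of 25 genes of mitochondrial import, chaperones and proteases, 23 were higher and 1 lower (median 1.36), with TOMM40 up by 2.34, TIMM50 up by 2.07 and the protease gene CLPP at −0.30 (glmTreat adjusted p = 1). Camera gave adjusted p = 2.59e-14, 1.04e-04 and 1.76e-07 for the 3 lists. With an estimated correlation the adjusted p was 0.251, 0.0792 and 0.234.

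Antioxidant, peroxisomal and fuel-handling genes moved mostly upward. Of 21 antioxidant and uncoupling genes, 16 were higher and 3 lower (median 0.76, camera adjusted p = 0.00211, adjusted p = 0.4999 with an estimated correlation). SOD2, the mitochondrial superoxide dismutase, rose from 86.6 ± 0.850 to 854 ± 13.2 CPM (3.30 on the log2 scale) and the peroxiredoxin gene PRDX2 rose by 1.89, whereas the stress-response gene SESN2 fell by 1.74. Of 31 peroxisomal genes, 26 were higher and 3 lower (median 0.69, camera adjusted p = 6.00e-05, adjusted p = 0.0792 with an estimated correlation), among them CRAT, carnitine acetyltransferase, at 3.15 and PEX3, a membrane biogenesis factor, at 2.33 (log2), with CROT at −1.42. Of 24 fuel-switching and muscle-type target genes, 19 were higher and 5 lower (median 1.22, camera adjusted p = 0.00185, adjusted p = 0.0792 with an estimated correlation). LDHD, a D-lactate dehydrogenase, rose by 6.57 and SLC2A4, the insulin-responsive glucose transporter GLUT4, by 6.10, while PLN, phospholamban, fell from 705 to 94 counts over the group. Of 20 glycolytic genes, 13 were higher and 6 lower (median 1.00, camera adjusted p = 0.0395). That call did not hold with an estimated correlation (adjusted p = 0.583) or with the replicate block (adjusted p = 0.0510). GPI, glucose-6-phosphate isomerase, rose by 2.25 and the lactate carrier SLC16A1 by 2.08, while hexokinase HK2 fell by 1.28.

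Nuclear receptors and cholesterol genes were split. Of 32 nuclear receptor and PGC-1 partner genes, 16 were higher and 12 lower, with a median of 0.15 that turned to −0.18 with total counts (camera adjusted p = 0.347). ESRRB rose by 5.98 (0.173 to 11.4 CPM) and the corepressor gene NRIP1 rose by 3.01, while the retinoid receptor gene RXRA fell by 2.17. Of 23 cholesterol synthesis and uptake genes, 13 were higher and 8 lower, with a median of 0.14 that turned to −0.19 with total counts (camera adjusted p = 0.347). EBP and DHCR7, both late enzymes of the pathway, rose by 2.15 and 1.64, and HSD17B7 fell by 0.92.

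Genes of catecholaminergic identity and neurite growth fell. Of 21 catecholaminergic genes, 16 were lower and 3 higher, with a median log2 fold change of −0.93 (camera adjusted p = 5.38e-04, adjusted p = 0.0792 with an estimated correlation). Besides SLC18A1, DBH, the enzyme that makes noradrenaline, fell by 3.26 (127 ± 1.70 to 13.2 ± 1.64 CPM), while CHGA, chromogranin A of secretory granules, rose by 1.57. Of 26 genes of neurite growth and neuronal differentiation, 24 were lower and 1 higher, with a median of −1.21 (camera adjusted p = 4.57e-06, adjusted p = 0.167 with an estimated correlation). GAP43, a growth cone protein gene, fell by 3.33 (149 ± 1.13 to 14.8 ± 0.497 CPM) and STMN4, of the stathmin family, fell by 3.18. MAPT, which encodes tau, was at 0.41, a change that did not pass with total counts (adjusted p = 0.0982) or against a 1.5-fold change (glmTreat adjusted p = 1). Synaptic release and neurofilament genes divided, with 13 of 28 higher and 14 lower; their median was −0.25, their mean 0.59 and the direction of camera upward (adjusted p = 0.884). SYT2, the synaptotagmin of fast synapses, rose from 1.09 ± 0.191 to 102 ± 1.25 CPM (6.54 on the log2 scale) and the complexin gene CPLX1 rose by 4.21, while SV2C fell by 2.27. SYT2 shares 27.2% of its exon bases with genes on either strand.

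Markers of other neuroblastoma and glial cell states were measured beside these. Of 27 markers of substrate-adherent, mesenchymal-type neuroblastoma cells, 23 were lower and 2 higher (median −0.89, camera adjusted p = 8.50e-05, adjusted p = 0.0792 with an estimated correlation). The matrix genes LUM and COL1A2 fell (−3.17 and −2.70 on the log2 scale), and COL6A1 rose by 1.96. Of 8 Schwann cell and glial markers tested, 5 were higher and 3 lower (median 0.96, mean 0.06, camera upward, adjusted p = 0.841). The direction turned downward with fry (adjusted p = 4.59e-04), with the filter of 1 CPM (camera adjusted p = 0.767) and without GFP replicate 3 or any 1 PGC1A library (0.897 to 0.959). ITGB4 rose by 1.82 and NGFR by 1.39; NGFR shares 27.1% of its exon bases with genes on either strand.

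Innate immune and stress genes showed no common rise. Of 25 interferon-stimulated genes, 9 were higher and 13 lower (median −0.57, mean −0.04, camera adjusted p = 0.546, with fry pointing upward). OAS1 fell by 2.00, BST2 fell by 1.86 and IFI27 rose by 4.06. Of 9 NF-kB and inflammatory genes, 3 were higher and 5 lower (median −0.54, camera adjusted p = 0.389), against 0 and 6 with total counts. CCL2 fell by 0.70, NFKB1 changed by −0.61 (glmTreat adjusted p = 0.237) and ICAM1 by 0.58, which did not pass with total counts (adjusted p = 0.0844) or against a 1.5-fold change (glmTreat adjusted p = 0.458). ICAM1 shares 23.6% of its exon bases with genes on either strand. Of 24 p53 targets, 9 were higher and 15 lower (median −0.28, camera adjusted p = 0.203), against 5 and 18 with total counts. The pro-apoptotic gene BBC3 was at −1.74, the kinase gene PLK2 at −1.38 and FDXR, a mitochondrial ferredoxin reductase gene, at 1.71. Of 31 genes of the integrated stress and unfolded protein responses, 22 were lower and 6 higher (median −0.62, camera adjusted p = 0.00237, adjusted p = 0.288 with an estimated correlation). NUPR1 fell by 1.59 and CHAC1 fell from 13.8 to 4.87 CPM, while ASNS, with 44.6% of its exon bases in another gene, rose by 0.73.

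Cell cycle lists had medians near 0, and histone genes fell. Of 29 S phase genes, 10 were higher and 14 lower (median −0.08, camera adjusted p = 0.525), against 5 and 23 with total counts; MCM7 fell by 1.17, UHRF1 fell by 1.05 and MCM4 rose by 1.10. Of 29 G2/M genes, 8 were higher and 18 lower (median −0.17, camera adjusted p = 0.327), against 2 and 24 with total counts. The kinase gene AURKA rose by 1.89, while CDC25B and NUSAP1 were at −0.49 and −0.55 and passed no test against a 1.5-fold change (glmTreat adjusted p = 1 and 0.832); NUSAP1 has 62.2% of its exon bases in another gene. Of 19 replication-dependent histone genes, whose mRNAs normally lack a poly(A) tail, 17 were lower and 0 higher (median −2.83, camera adjusted p = 6.32e-06, adjusted p = 0.0792 with an estimated correlation). After H4C5, H2AC13 fell by 4.11 (9.11 to 0.522 CPM). Histone genes have near-identical copies, so their counts are uncertain.

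Lysosomal, Parkinson disease and ribosomal genes completed the lists. Of 37 lysosome and autophagy genes, 21 were higher and 12 lower (median 0.36, camera adjusted p = 0.124), against 18 and 18 with total counts. The transcription factor gene MITF rose by 3.48 and WIPI1 by 3.08, while the mitophagy receptor gene BNIP3L fell by 1.68; WIPI1 shares 28.1% of its exon bases with genes on either strand. Of 19 Parkinson disease genes, 9 were higher and 8 lower, with a median of −0.03 that turned positive with DESeq2-type size factors, a mean of 0.23 and an upward direction in camera (adjusted p = 0.783). With total counts 6 were higher and 13 lower, the median was −0.36 and camera pointed downward (adjusted p = 0.938). CHCHD10 and CHCHD2, mitochondrial intermembrane space proteins, rose by 2.48 and 1.45, and UCHL1, an abundant neuronal deubiquitinase, fell by 1.23; CHCHD10 shares 18.1% of its exon bases with genes on either strand. Cytosolic ribosomal protein genes were listed with RNA quality in mind, but RNA integrity itself was not analysed here. Of 85 such genes, 61 were lower and 14 higher (median −0.28, camera adjusted p = 0.00103, adjusted p = 0.660 with an estimated correlation), a change smaller than the shift between scalings. With upper-quartile factors 7 were higher and 69 lower, and with total counts 3 were higher and 80 lower (median −0.61). RPLP0 and RPL13 fell (−0.86 and −0.82), and RPL26L1 rose by 0.96. These genes have many pseudogene copies that share reads. For all 28 lists the counts adjusted over the list alone equalled those over all genes tested. Camera called 17 of the 28 lists. With an estimated correlation it called 0 (8 at an unadjusted p under 0.05), and fry called 27. Some lists lost their call although the estimate lay below the preset 0.01. These were peroxisome (−0.0131), fuel switching (−0.0173), catecholaminergic identity (−0.0332), mtDNA maintenance (0.00348) and replication-dependent histones (0.00301). For them a stronger correlation between members is not what ended the call. The estimated version tests on only 4 residual degrees of freedom, which raises its p-values whatever the correlation. In the simulation of independent genes, camera gave the shifted list an adjusted p of 8.24e-04 with that version and 9.48e-82 with the preset. A call lost with an estimated correlation is therefore not by itself evidence of correlated members. Other called lists had higher estimates, up to 0.673 for cytosolic ribosomal proteins.

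**Figure D3:**
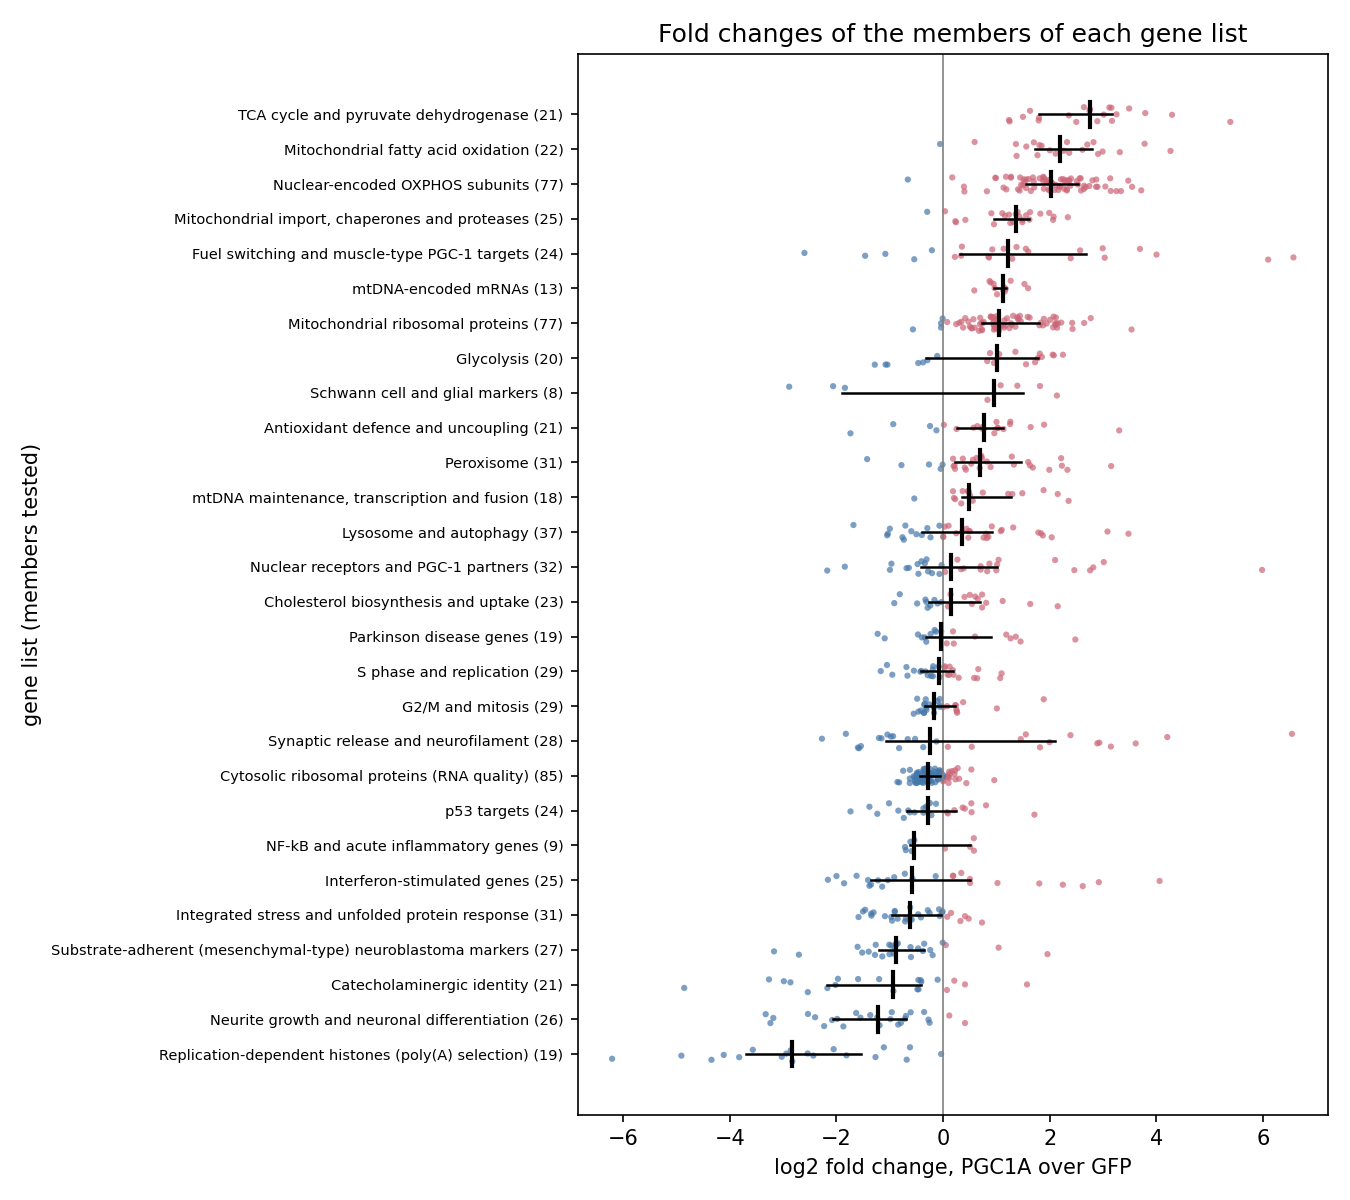
Log2 fold change of PGC1A over GFP for each tested member of the 28 gene lists (points, red above 0 and blue below), with the list median (vertical tick) and quartiles (horizontal line); the number of tested members stands in parentheses. The TCA list had the highest median, 2.76, and the replication-dependent histones the lowest, −2.83; with total counts the nuclear receptor and cholesterol medians changed sign, and with DESeq2-type size factors the Parkinson median did.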

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

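The tests of scaling, of a shift toward substrate-adherent cells, of poly(A) capture and of S phase were chosen only after the result each bears on had been seen.

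Reads left ambiguous between overlapping genes lie outside the gene counts, and their share was higher in PGC1A than in the control libraries: 7.01% ± 0.022 of the reads in the table against 6.73% ± 0.108 (SD, n = 3). The exact permutation p was 0.1, the smallest that 3 against 3 libraries allow.

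The split of the 6 libraries by group gave 16057 genes past an adjusted p of 0.05, and the highest of the 9 other splits into 3 and 3 gave 0 with the same edgeR test (30 to 40 genes at an unadjusted p under 0.05). The real split was the only 1 of the 10 to give as many, and 10 splits are too few for a share under 0.05. Each other split mixed libraries of both groups, which puts the group difference into the spread within its groups. Few calls follow from that, so these splits do not measure the rate of false calls.

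In all, 115 genes with 3 or fewer counts over the GFP libraries reached 1 CPM or more in PGC1A (median 2.54 CPM), against 7 that went the other way. RNA from placenta, epidermis or muscle would bring the abundant transcripts of that tissue, but of the 3 lists the highest median was 0.165 CPM in the PGC1A libraries. CSH1, CSH2, KRT1 and KRT5 had no counts in either group. Above that median in PGC1A were CGA (8.62 CPM, from 42 to 678 counts), CKM (from 10 to 629 counts) and MB (from 0.386 to 3.15 CPM). TNNT1 (from 4.74 to 12.8 CPM) and KRT10 (from 20.4 to 38.9 CPM) were also above it and were already expressed in GFP. Read-through from a risen gene that ends within 50 kb upstream on the same strand would apply to 10 of the 114 genes with coordinates, 8.77% (exact 95% interval 4.29 to 15.5), beside 6.86% of other tested genes. Neither read-through nor RNA of those 3 tissues accounts for the set as a whole. RNA from other tissues was not tested, reads shared among paralogs stay open for the PSG, KLK and CEACAM families, and a response of silent genes to the very high PGC-1a level may be a candidate explanation that these data cannot separate from other effects of this virus.

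The neurite growth and catecholaminergic lists joined had a median log2 fold change of −1.19 over 47 genes. The highest median over the scalings run was −1.15, taken as this median plus the shift of all genes under each scaling. The largest upward shift was 0.036 (log2), with DESeq2-type size factors, so these scalings could not have brought the median to 0. Removing the trend of fold change on exon length and GC content left −1.14. A shift from neuronal-type to substrate-adherent cells would raise the markers of the latter, whose median was −0.89. A loss of neuronal and catecholaminergic transcripts as a response to PGC-1a may be one explanation. The integrated stress and unfolded protein response list had a median of −0.62 (upper quartile −0.04). The p53 targets had a median of −0.28 (upper quartile 0.25), with 9 of 24 higher, or 5 of 24 with total counts. Unequal virus dose stays open, since no titre is given.

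Replication-dependent histone genes fell with a median of −2.83. Fewer cells in S phase would lower the S phase and replication list, whose median was −0.0818 with a lower quartile of −0.41. Weaker capture of RNA without a poly(A) tail cannot be told apart from a lower level: 11 small RNAs outside other genes had a median of 0.0373 and a lower quartile of −0.71, above the bound of −1.5 set for excluding it, but that bound was wrong for genes at a median of 0.448 CPM, near the floor. Replication-independent histone genes, whose mRNAs carry tails, were lower in 6 of 7 cases with a median of −1.10, H3-3B among them at −1.10. A lower level of histone mRNA of both kinds may therefore be part of the pattern.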

How the results depend on the processing

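All alternatives were chosen before the data were examined. PPARGC1A, the direction of all 94 named genes and the shift between nuclear and mtDNA lists kept their direction under every alternative run for them, and 84 of the 94 genes passed against a 1.5-fold change and 92 with total counts. The count of genes past the threshold was 9241 with glmTreat (4766 higher, 4475 lower), which asks for a larger change by construction, and genes at least 2-fold lower numbered 4944 with total counts, which shift all genes by −0.33. With total counts 720 of the 14646 shared calls had the opposite sign. Lists called as sets numbered 17 with camera, 0 with an estimated correlation and 27 with fry, which does not compare a list with other genes. Directions of uncalled lists turned for Parkinson genes with total counts (adjusted p = 0.938), for Schwann and glial markers with the filter of 1 CPM (0.767), with fry (4.59e-04) and without GFP replicate 3 or any 1 PGC1A library (0.897 to 0.959), though not without GFP replicate 1 (0.824) or 2 (0.841), and for interferon genes with fry (0.0135); the cause was not tested. Beyond these, G2/M passed with total counts (0.0245) and lysosome genes without the filter (0.0393), and fry passed 8 further lists beside those named. The replicate numbers showed no sign of pairing the libraries: deviations of same-numbered libraries correlated at −0.0114, 0.00628 and 0.0109, and 2 of 6 libraries matched their own number best. A pairing with effects smaller than the noise in these deviations cannot be excluded. The replicate block gave 16071 genes, 16025 of them shared with the 16057, and ended the call of glycolysis (0.0510) only. DESeq2 shared 14970 calls, and leaving out 1 library kept 15462 to 15595. The main filter left 38753 rows untested for low or absent counts. Without it the 38779 of 58096 rows with at least 1 count were tested, and 15735 of the calls were shared.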

Other observations

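The comparisons of gene families and of chromosomes were chosen after the data had been seen. Genes were grouped by symbol stem, and 473 families with at least 5 tested members were compared with camera at the preset correlation; 25 passed, and 0 did with an estimated correlation (lowest adjusted p = 0.791; 17 at an unadjusted p under 0.05). All 11 COQ genes, which make or regulate ubiquinone, were higher (median log2 fold change 1.25, adjusted p = 0.00626), COQ10A the most at 2.88, and COQ8B at 0.12 is smaller than the −0.33 shift of total counts. All 9 tested subunits of the endoplasmic reticulum membrane complex were higher (median 1.27, adjusted p = 0.0181), EMC3 by 1.89, although EMC1 at 0.08 is within that shift. All 10 pregnancy-specific glycoprotein genes rose (adjusted p = 0.00209), from 0 to 5.67 CPM in GFP to between 1.71 and 48.9 CPM in PGC1A, with PSG4 and PSG9 the highest. Of 8 kallikrein genes tested 7 rose (adjusted p = 0.0112), KLK1 from 2 counts to 2085 (ratio 1284, 95% counting interval 355 to 10611) and KLK11 from 0 to 1032 counts. Most risen PSG and KLK members had 0 to 2 counts over the GFP libraries, so they passed the filter only through PGC1A and could only be called higher. Family members with too few counts in both groups were not tested. The shares and p-values of these families were therefore partly fixed by the filter.

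Clustered protocadherins and contactins, cell adhesion molecules of neurons, went down. Of 19 PCDHG genes 18 fell (median −1.94, adjusted p = 0.00224), and of 15 PCDHB genes 14 fell (median −1.73, adjusted p = 0.00675). Of 11 PCDHA genes 9 fell and 1 rose, with a similar median of −1.69, although they did not pass as a family (adjusted p = 0.0963). All 6 CNTN genes were lower (median −2.25, adjusted p = 0.0321). PSG, KLK and protocadherin genes share sequence or exons with their neighbours, which makes single members uncertain. Of 6 metallothionein genes tested, picked after their values were seen, 5 were higher and 1 lower, and they did not pass as a family (adjusted p = 0.234). MT3, the brain form, went from 1 count to 2698 (34.3 CPM) and MT2A rose from 26.8 to 181 CPM, whereas MT1E fell by 0.66 on the log2 scale.

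Within the split synaptic and neurofilament list, the neurofilament gene NEFH rose by 3.15 (86.5 to 766 CPM), while NEFM fell by 0.37. NEFH and NEFM were named after their values were seen.

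The genes that came on were concentrated on chromosome 19. Of 81 coding genes that came on, 27 lie there (33.3%), against 272 of 3832 other coding genes with 3 or fewer GFP counts (7.10%); Fisher's exact test gave an odds ratio of 6.54, two-sided p = 1.19e-11, or 2.74e-10 adjusted over 23 chromosomes. The hypothesis that this may go beyond the PSG, KLK and CEACAM clusters was tested by leaving them out: 12 of 66 genes (18.2%) against 258 of 3818 (6.76%), odds ratio 3.07, exact p = 0.00165. Neighbouring genes are not independent, so these p-values are too small, and 3 neighbouring pairs remain among the 12: DMKN and SBSN, LGALS13 and LGALS16, and RASAL3 and PGLYRP2. With neighbours within 50 kb counted once, 9 of 62 groups of genes that came on (14.5%) lie on chromosome 19 against 119 of 2187 (5.44%), odds ratio 2.95, exact p = 0.00732. Chromosome 19 was the most extreme of the 23 in these same data. The p-values without the families are not adjusted for that choice, so a concentration beyond the families remains uncertain.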
